A study of Mus musculus with 3 samples.

How the data were processed

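Single-cell RNA was measured in 3 libraries, 1 per host genotype, from LLC1 tumours (a mouse Lewis lung carcinoma line) grown in the tibia. Per the labels' protocols, 1000000 cells in 10 µL were injected into 8-week-old wild-type, DMP1-Cre Mfn2 knockout or DMP1-Cre Rhot1 knockout mice, and tumours were taken on day 14. Dissociation used collagenase type IV at 2 mg/ml for 1 h and a 70 µm filter, and live cells were sorted by exclusion of a viability dye. Each library pooled tumours of 3 mice in equal parts, and the files used here hold no map from cells to mice, so each pool was treated as 1 sample.

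The deposited matrices hold whole UMI counts per gene and barcode. They were written by Cell Ranger 7.0.0, per the file headers, and the genome build was mm10, per the submitters' processing notes. The gene annotation and the setting for intronic reads are not given in the sources used here. Of 55357 gene identifiers in the files, 52081 (94.1%) were found in GENCODE M21, which was used for coordinates and for sequence matching only.

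Cells with 300 or more genes and at most 15% of UMIs from mt- genes were kept. Scrublet, run per library with its automatic threshold, marked 295, 394 and 292 cells (3.17%, 3.99% and 3.12%) in the wild-type, Mfn2 and Rhot1 libraries, and these were removed. This left 9000, 9474 and 9067 cells. Counts were log-normalised to 10000 UMIs, 2000 variable genes and 30 principal components were taken with scanpy 1.11.5, and a graph of 15 neighbours with shared-neighbour weights was clustered jointly with leidenalg 0.10.2 at resolution 1, giving 28 clusters. No integration between libraries was applied.

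Clusters were named from marker sets fixed before the data were examined. The rule that scored a cluster against those sets was revised after the data were seen, because comparing a cluster with all other cells misnamed clusters of the most abundant class. The rule used compares a cluster with the equally weighted mean of coarse groups. Clusters stayed unnamed when more of their leading genes marked another class than their best one, when they were much shallower than their coarse group, or when they were shallow within the libraries and had no leading marker. Unnamed clusters held 14.2%, 8.62% and 11.1% of kept cells in the wild-type, Mfn2 and Rhot1 libraries. Most of these carried tumour markers, so shares are also given with those clusters added.

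With 1 library per genotype there was no test between genotypes, and no p-value or standard error was computed. Shares have exact Clopper-Pearson 95% intervals, UMI levels exact Poisson 95% intervals, and ratios of counts exact conditional intervals. Intervals of share ratios are log-normal and those of list medians come from 200 Poisson draws. All of them cover counting error only, and none covers the variation between mice, tumours or sorts. Intervals of UMI levels, count ratios and list medians treat UMIs as independent. They therefore also leave out variation between cells, and are too narrow where few cells hold most UMIs of a gene. Where a count was 0, the share that 3 counts would give is printed as the limit.

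Within a class, UMIs were summed per gene and library and expressed as counts per 1000000 of the class total (CPM). Log2 ratios used a pseudocount of 5 CPM. List medians used members at 10 CPM or more in at least 1 of the libraries compared, and members were counted as higher or lower at a log2 ratio of 0.32 or more in size, without pseudocount. Each median is placed among 10000 random lists of the same size matched on mean expression in 20 bins, as a description of these libraries. Named genes followed a rule fixed before the data were examined. In tumour-like cells these are the 8 highest and 8 lowest ratios among genes at 50 CPM or more, and in macrophage-, neutrophil- and T cell-like cells the 2 highest and 2 lowest. Genes much lower in the class than over all cells, and mitochondrial, ribosomal protein, haemoglobin, immunoglobulin and unnamed gene models, were left out of this ranking. Of each list described, the 2 highest and 2 lowest members could be named. Both knockout comparisons share the wild-type library, so their covariance over genes is given beside the mean of 100 simulations of unchanged groups with Poisson counts.

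The steps were tested on class totals simulated with Poisson counts and 200 genes changed. The intervals assume such counts, so this checks the computation and not UMIs clumped in single cells. Intervals held the true ratio for 95.3% of 8051 genes in tumour-like cells and 96.3% of 8467 genes in T cell-like cells, for Mfn2 over wild type. Changes of 0.32 on the log2 scale were recovered for 100.0% of the changed genes in tumour-like cells, 78.0% in macrophage-like cells, 16.0% in neutrophil-like cells and 12.0% in T cell-like cells of that comparison. Up to 3 of 28 unchanged lists fell in the outer 5% of random lists.

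Alternatives fixed before the data were examined changed the cell filter, doublet removal, clustering, cell classing, depth (each cell thinned to 1500 UMIs, which left out 966, 1157 and 853 cells), denominators, pseudocount, expression minimum and scaling, including edgeR 4.0.16 TMM factors and DESeq2 1.42.0 size factors on the class sums. Others were chosen after the data were seen: adding the unnamed tumour-marker clusters, leaving out a small deep neutrophil-like cluster, and leaving out the cell with most UMIs of a gene or list. The combined share of macrophage- and monocyte-like cells was also added after the separate shares were seen. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and R 4.3.3 were used.

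Mitochondrial levels need care in these counts. Stretches of 90 bases from the last 500 bases of mitochondrial genes were searched in nuclear transcripts, and mt-Co2, mt-Co3 and mt-Nd3 shared 99.3%, 99.8% and 97.7% of theirs. These genes had 8.20, 11.2 and 0.900 CPM in wild-type tumour-like cells, so the mitochondrial share per cell may be understated and the filter on it lenient. Sharing does not account for all levels, since mt-Co1 shared 94.9% and had 633 CPM, while mt-Nd6 shared none and had 23.5 CPM.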

Results

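LLC1 tumours grown in the tibia of wild-type mice and of mice with DMP1-Cre deletion of Mfn2 or Rhot1 were profiled by droplet 3' single-cell RNA sequencing on day 14. Mfn2 encodes mitofusin 2, a GTPase of mitochondrial outer-membrane fusion, and Rhot1 encodes Miro1, a GTPase that links mitochondria to the transport machinery. Dmp1-Cre acts in osteocytes, so the design compares tumours and infiltrating cells of hosts whose bone cells, and not the injected cells, should carry the deletion. The control is labelled wild type with no Cre named, so carrying Cre cannot be told apart from the deletion in either comparison. There was 1 library per genotype, each pooling 3 mice, so no difference given here has a replicate check, and intervals in parentheses are 95% intervals of counting error only. The wild-type, Mfn2 and Rhot1 libraries held 9393, 10016 and 9534 barcodes with 112088653, 118123705 and 118223251 UMIs, and median depths of 9927, 10860.5 and 12024 UMIs per barcode.

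The targeted genes were not lower in the libraries that carry their names. Mfn2 (ENSMUSG00000029020, mm10 chromosome 4, 147873599 to 147904704) stood at 16.2 CPM (15.5 to 17.0) over all kept wild-type cells, 20.2 (19.4 to 21.1) in the Mfn2 library and 20.6 (19.8 to 21.5) in the Rhot1 library. Rhot1 (ENSMUSG00000017686, chromosome 11, 80209019 to 80267907) stood at 23.1 CPM (22.2 to 24.0), 23.8 (22.9 to 24.7) and 25.2 (24.3 to 26.1). No cluster was osteocyte-like, and Dmp1 itself had 9, 6 and 3 UMIs. Osteocytes were therefore not measured as a class here, and whether any kept cells carry a deletion is not known. A 3' tag can also lie outside a deleted part, so these levels do not check the genotypes.

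Tumour-like cells, with Krt8, Krt18 and Hmga2 among their markers, made up a larger share of both knockout libraries. They were 47.2% of wild-type cells (46.2 to 48.2), 60.7% of Mfn2 cells (59.7 to 61.7) and 61.3% of Rhot1 cells (60.3 to 62.3). With the unnamed clusters that carried tumour markers added, the shares were 59.4%, 67.5% and 69.6%, a smaller gap. Most of that change came from cluster 13, which was led by Mmp3, Lum and Dcn, genes named here after their values were seen, and held 7.31% of wild-type cells, 0.897% of Mfn2 cells and 1.05% of Rhot1 cells. When each library was clustered on its own the log2 ratio of Mfn2 over wild type was -0.09, against 0.36 with joint clustering, so the direction of this share depends on how cells are classed.

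T cell-like cells formed smaller shares in both knockout libraries, as did NK, dendritic and B cell-like cells with joint clustering. T cell-like cells were 3.32% of wild-type cells (2.96 to 3.71), 1.02% of Mfn2 cells (0.831 to 1.248) and 1.72% of Rhot1 cells (1.46 to 2.01). NK cell-like cells were 1.24%, 0.380% and 0.673%, dendritic cell-like cells 1.81%, 0.559% and 0.960%, and B cell-like cells 0.489%, 0.158% and 0.199%. Among cells outside all tumour-marker clusters, T cell-like shares were 8.19%, 3.15% and 5.66%, which are ratios to wild type of 0.385 (0.307 to 0.481) and 0.692 (0.574 to 0.834). Classing each cell by its highest marker score gave log2 ratios for Mfn2 and Rhot1 of -0.036 and 0.13 for NK cell-like cells. They were -0.57 and -0.081 for dendritic cell-like cells and 0.25 and 0.70 for B cell-like cells. The lower NK and B cell-like shares therefore did not hold under that scoring. It left no cell unnamed and called only 14.1%, 21.4% and 19.7% of wild-type, Mfn2 and Rhot1 cells tumour-like. Its other classes may therefore hold many tumour cells, which limits what these values show. The dendritic cell-like share stayed below wild type under every alternative run.

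Macrophage-like and monocyte-like cells together were 23.7% of wild-type cells, 19.2% of Mfn2 cells and 18.9% of Rhot1 cells. Outside tumour-marker clusters their shares were 58.4%, 59.2% and 62.2%, so the lower share of all cells did not hold among the other cells. With each library clustered on its own, the log2 ratios of monocyte-like shares were 0.34 and 0.74 for Mfn2 and Rhot1 over wild type. Neutrophil-like cells were 7.64% (7.10 to 8.21), 9.28% (8.70 to 9.88) and 5.06% (4.62 to 5.53) of kept cells. Outside tumour-marker clusters they were 18.8%, 28.5% and 16.7%. Their median depth was 1144 UMIs in the wild-type library, and thinning to 1500 UMIs left most of them out and turned the Mfn2 log2 ratio from 0.28 to -0.066. With each library clustered on its own the Rhot1 log2 ratio was -5.29, against -0.59 with joint clustering. Osteoclast-like cells numbered 21 in the wild-type library, 3 in the Mfn2 library and 0 of 9067 in the Rhot1 library. There 3 counts would be a share of 0.0331%, and the exact upper bound was 0.0407%. These are cells of a named cluster. A Rhot1 cell classed as neutrophil-like held 106 UMIs of the osteoclast gene Acp5, so such cells may lie in other clusters.

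**Figure D1:**
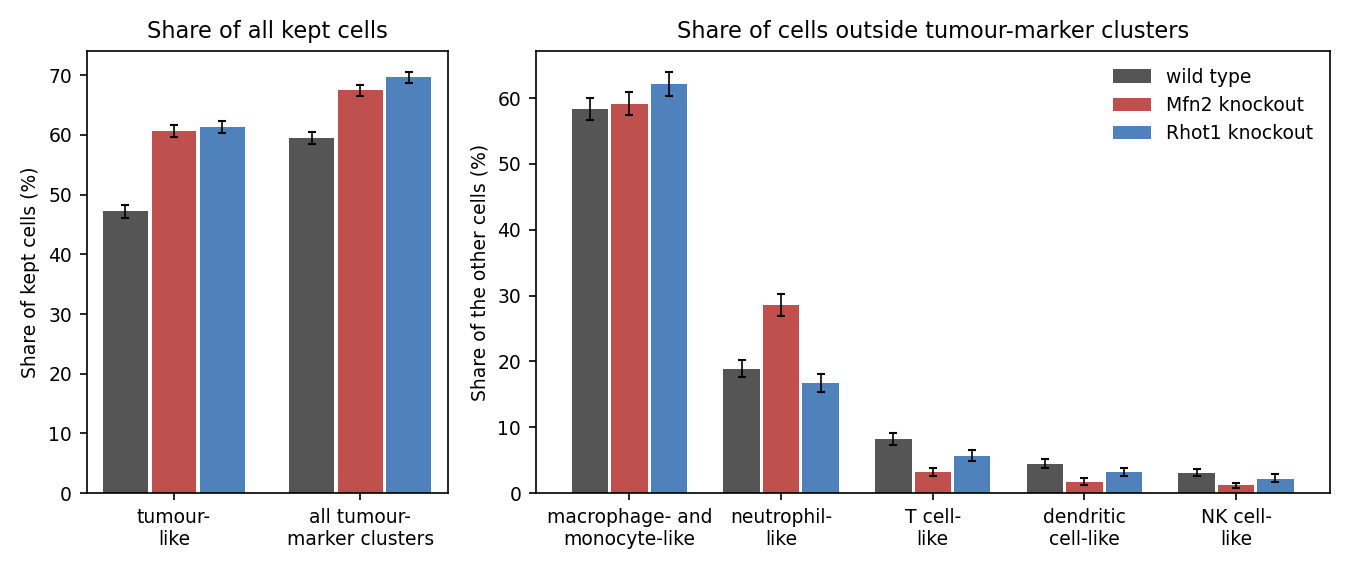
Shares of cell classes in percent, with tumour-like cells and all tumour-marker clusters over all kept cells on the left and other classes over cells outside tumour-marker clusters on the right. Bars are single libraries and error bars are exact binomial 95% intervals, and T cell-like cells were 8.19%, 3.15% and 5.66% of the other cells in the wild-type, Mfn2 and Rhot1 libraries.

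In tumour-like cells of the Mfn2 library, the polyamine enzyme genes Odc1 and Sat1 were among the highest ratios to the wild-type library, and some matrix genes were among the lowest. Odc1, the rate-limiting enzyme of polyamine synthesis, stood at 3161 CPM against 1775, a ratio of 1.78 (1.77 to 1.79), and Sat1, which acetylates polyamines, at 409 against 213 CPM. Prxl2a, a peroxiredoxin-like protein, had the highest ratio at 4.30 (4.18 to 4.42). Next were Ecm1 at 2.03, the purine enzyme Xdh at 2.07, Cpe at 1.82, Gpnmb at 1.76 and the calcineurin regulator Rcan1 at 1.80. The lowest ratios were those of lumican (Lum, 0.373), the collagen genes Col6a3 (0.399) and Col3a1 (0.583), the stress-response transcription factor Atf3 (0.438), Gng11 (0.497), the gene model Mir6236 (0.535), Tmem176b (0.538) and Arhgap6 (0.538). Atf3 is a member of the dissociation stress list, whose lower values cannot be told apart from handling of the suspensions. This class leaves out cluster 13, and with the unnamed tumour-marker clusters added Lum had a ratio of 0.206 and fibronectin (Fn1) the lowest, 0.167. With clusters weighted alike the log2 ratio of Lum was -0.74, against -1.28. The mix of tumour-like clusters differed, with cluster 3 at 23.1% of the class in the wild-type library, 6.91% in the Mfn2 library and 11.6% in the Rhot1 library, and cluster 0 at 15.8%, 24.7% and 26.5%. Within the 8 tumour-like clusters taken singly, the Prxl2a ratio ran from 2.87 to 7.04 and the Odc1 ratio from 1.21 to 2.05. In cluster 13, outside the class, Odc1 had ratios of 1.03 and 0.993 for Mfn2 and Rhot1, with intervals that held 1, and Prxl2a 1.62 and 1.24.

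Interferon-stimulated genes had a median log2 ratio of -0.37 (-0.45 to -0.33) in tumour-like cells of the Mfn2 library, with 8 of 13 measured members lower and 0 higher, below all 10000 matched random lists. Cxcl10, a chemokine that attracts T cells, stood at 5.74 CPM against 19.1, and Rsad2 at 6.26 against 13.5, while Ifi35 and Oasl1 had ratios of 1.01 and 1.08. The tumour-like cluster led by these genes, cluster 17, held 3.23% of the class in the wild-type library, 1.58% in the Mfn2 library and 2.92% in the Rhot1 library. With clusters weighted alike the median was -0.13. The list of the cGAS-STING pathway, which senses cytosolic DNA, had a median of 0.03 (-0.00 to 0.06). Cxcl10, given above at 5.74 against 19.1 CPM, is also a member of this list. Other members included Sting1 at a ratio of 0.869, Tbk1 at 1.04, Tmem203 at 1.29 and Ccl5 at 1.52.

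MHC class I presentation genes had a median of -0.15 (-0.18 to -0.13) in the same comparison, with 4 of 16 lower, Psmb9 lowest at a ratio of 0.599 and H2-K1 at 1.00. NF-kB targets had a median of -0.22 with 4 of 14 lower, among them Il1b at 0.507 and Nfkbia at 0.669. Chemokines and colony-stimulating factors had a median of -0.24, with Il33 at 9.49 against 36.8 CPM and Ccl5 at a ratio of 1.52. With the stricter cell filter the NF-kB and chemokine medians were both -0.061. Glycolysis genes had a median of 0.25 (0.24 to 0.27), above all random lists, with 5 of 15 higher, including the glucose transporter gene Slc2a1 at 1.38 and Pfkfb3 at 1.48. Hypoxia genes had a median of 0.19, and mitochondrially encoded genes 0.28 (0.22 to 0.29) with 4 of 11 higher and 1 lower. Nuclear oxidative phosphorylation genes had a median of -0.12, with 1 of 39 lower. Medians were -0.20 for the unfolded protein response, -0.12 for dissociation stress (0.0050 with cells thinned to 1500 UMIs), -0.07 for matrix and mesenchymal genes (4 of 13 lower and 1 higher) and 0.03 for mitochondrial dynamics and transport. S phase and G2/M phase genes had medians of -0.08 and -0.07, which turned above 0 at Leiden resolution 0.5 (0.009 and 0.04).

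Tumour-like cells of the Rhot1 library shared the higher Odc1 and Prxl2a and the lower Lum, Col6a3 and Col3a1. Prxl2a had a ratio to wild type of 3.15 (3.06 to 3.24) and Odc1 of 1.63 (1.62 to 1.64). Dkk2, a regulator of Wnt signalling, stood at 1.70, Apobr at 1.63, Cpe at 1.62, Ahnak2 at 1.63, Xdh at 1.65 and the tubulin gene Tuba1c at 1.54. The lowest ratios were those of Atf3 (0.350), decorin (Dcn, 0.465), Col6a3 (0.473), Lum (0.478), Gng11 (0.549), Col3a1 (0.619), Tmem176b (0.606) and clusterin (Clu, 0.596). For Atf3 the limit on dissociation stress genes given above holds here too. With the unnamed tumour-marker clusters added, Lum had a ratio of 0.278 and Fn1 the lowest, 0.236, and with clusters weighted alike the log2 ratio of Lum was -0.55, against -0.97.

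Interferon-stimulated genes were closer to wild type in tumour-like cells of the Rhot1 library, with a median of -0.06 (-0.10 to -0.02), 2 of 13 lower and 0 higher. This median was 0.02 with clusters weighted alike and 0.26 with cells classed by marker score. MHC class I presentation genes had a median of -0.16, NF-kB targets -0.24, and chemokines and colony-stimulating factors -0.32, with Il33 at 4.93 against 36.8 CPM. Over the alternatives the NF-kB median ran from -0.44 to -0.084 and the chemokine median from -0.49 to -0.11. Mitochondrially encoded genes had a median of 0.30 (0.25 to 0.33), nuclear oxidative phosphorylation genes -0.08, glycolysis genes 0.05, hypoxia genes -0.16, dissociation stress -0.19, matrix and mesenchymal genes -0.13 (6 of 13 lower), and the unfolded protein response -0.07. S phase genes had a median of 0.10, G2/M phase genes 0.11, the cGAS-STING pathway 0.09, and mitochondrial dynamics and transport 0.12. The median of all genes tested was 0.05 in this comparison. Hypoxia genes turned to 0.10 with clusters weighted alike, and glycolysis genes to -0.01 with median-ratio scaling.

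**Figure D2:**
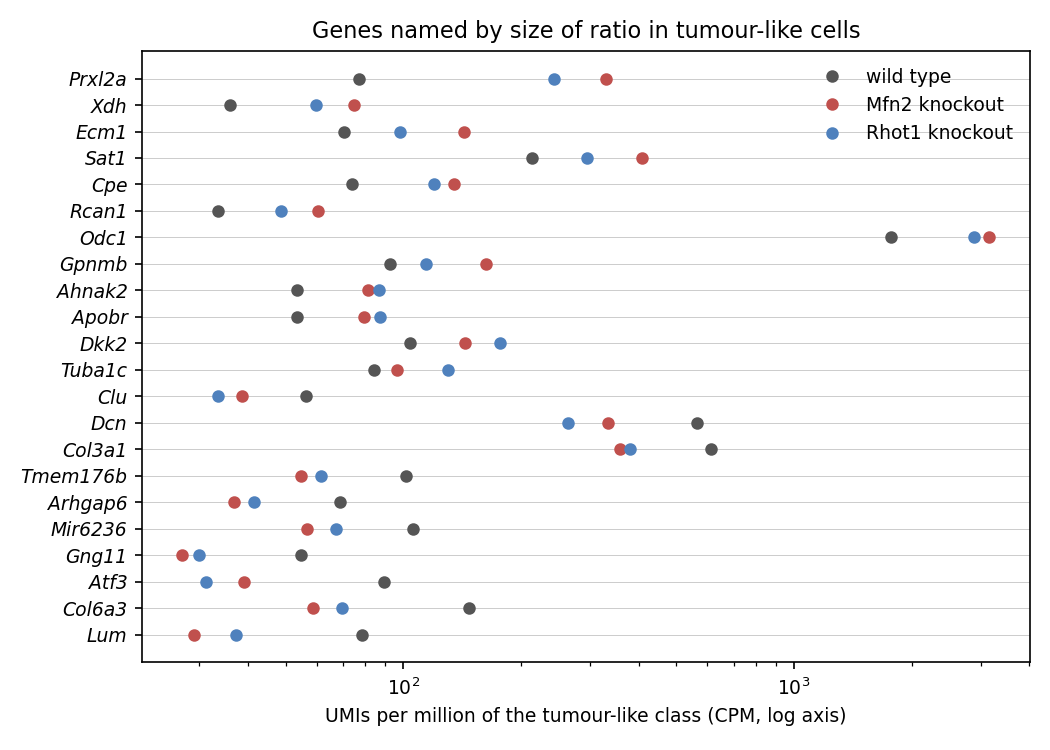
Level of each gene named by size of ratio in tumour-like cells, in CPM of the class on a log axis, with 1 point per library. Odc1 stood at 1775, 3161 and 2888 CPM in the wild-type, Mfn2 and Rhot1 libraries, and Lum at 78.2, 29.2 and 37.4 CPM.

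Macrophage-like cells carried less MHC class II and stress-response RNA in both knockout libraries. MHC class II presentation genes had medians of -0.59 (-0.62 to -0.53) in the Mfn2 library, with 9 of 9 lower, and -0.72 (-0.74 to -0.51) in the Rhot1 library, with 8 of 9 lower. H2-Eb1 stood at 767 CPM in the wild-type library, 457 in the Mfn2 library and 394 in the Rhot1 library. Dissociation stress genes, which cells switch on during enzymatic digestion, had medians of -0.44 and -0.46, with the heat shock gene Hspa1b at 203 CPM in the wild-type library against 78.3 and 63.0. Pro-inflammatory macrophage genes had medians of -0.36 and -0.26, NF-kB targets -0.38 and -0.13, and alternatively activated and tumour-associated macrophage genes 0.16 and 0.13. The last of these turned to -0.02 in the Mfn2 library when doublets were kept, and ran from 0.052 to 0.39 in the Rhot1 library over the alternatives.

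The knockout libraries differed from each other in several macrophage-like programmes. Interferon-stimulated genes had a median of 0.00 (-0.05 to 0.05) in the Mfn2 library, from -0.14 to 0.16 over the alternatives, and 0.41 (0.36 to 0.49) in the Rhot1 library, where 20 of 31 were higher, Ifit3b at a ratio of 3.52 and Cmpk2 at 2.15. The Rhot1 median was lowest, at 0.10, with each library clustered on its own. Cluster 18, led by the interferon-stimulated genes Rsad2, Cxcl10 and Ifit2, held 4.85% of the class in the wild-type library, 3.75% in the Mfn2 library and 7.83% in the Rhot1 library. Glycolysis genes had medians of 0.15 and -0.13, hypoxia genes -0.06 and -0.41, and G2/M phase genes -0.20 and 0.18. With doublets kept, the Mfn2 values for hypoxia and G2/M phase turned to 0.025 and 0.0015. The acute-phase gene Saa3 had a ratio of 8.47 (7.58 to 9.48) in the Mfn2 library, with 344 of its 2426 UMIs in 1 cell, and Wfdc21 3.52, while the costimulatory receptor gene Tnfrsf9 stood at 0.113 and Cd83 at 0.271. With doublets kept the log2 ratio of Tnfrsf9 was -1.08, against -2.47. In the Rhot1 library Ccl5 stood at a ratio of 2.30, with 255 of its 540 wild-type UMIs in 1 cell, and its log2 ratio of 1.14 became 1.83 without the cell with most of its UMIs in each library and 0.42 with cells classed by marker score. The haemoglobin scavenger receptor gene Cd163 had a Rhot1 ratio of 2.21, Hspa1b of 0.311 and Hspa1a of 0.334. The last 2 are dissociation stress genes, whose lower values cannot be told apart from handling of the suspensions. Of the 4 macrophage-like clusters, cluster 7 held 34.8% of the class in the wild-type library, 43.0% in the Mfn2 library and 24.5% in the Rhot1 library. Haemoglobin genes had medians of 2.84 and 2.37, and the Mfn2 value was 2.23 without the cell with most of these UMIs in each library. Whether these UMIs came from RNA of other cells was not tested. Monocyte-like cells had MHC class II medians of -0.64 and -0.19, dissociation stress medians of -0.29 and -0.37, and interferon-stimulated medians of 0.05 and -0.11, the last 2 with intervals that reached 0. With each library clustered on its own, the Rhot1 value for MHC class II turned to 0.51 and the Mfn2 value for interferon-stimulated genes to -1.35. The Rhot1 interferon-stimulated value ran from -0.21 to 0.41 over the alternatives.

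Neutrophil-like cells had lower NF-kB targets in both knockout libraries, while several other lists changed direction with the way cells were classed. NF-kB targets had medians of -0.77 (-0.97 to -0.64) in the Mfn2 library, with 14 of 18 lower, and -0.36 (-0.52 to -0.22) in the Rhot1 library, with 10 of 18 lower. Tnf stood at 13.6 CPM in the Mfn2 library against 62.9. Glycolysis genes had medians of 0.43 and 0.19, interferon-stimulated genes 0.20 and 0.28, and dissociation stress genes -0.31 and -0.27. The Mfn2 interferon-stimulated median turned to -0.039 with cells classed by marker score, and the Rhot1 median to -0.17 at Leiden resolution 2. With each library clustered on its own, only 18 Rhot1 cells were named neutrophil-like, and the Rhot1 medians were -1.94 for interferon-stimulated genes, -1.02 for glycolysis genes and -3.52 for mature neutrophil genes. Mature neutrophil genes had medians of -0.13 and 0.01, and granule genes -1.09 and -0.34. The granule medians turned to 0.92 and 0.61 without the small deep cluster 25, which held 24, 10 and 18 cells. The inducible nitric oxide synthase gene Nos2 had a ratio of 7.40 (4.79 to 12.0) in the Mfn2 library and Lipg 11.3. Elane had 655 UMIs in 5 wild-type cells, 1 in the Mfn2 library and 0 in the Rhot1 library. Mpo had 98 wild-type UMIs in 4 cells and 0 in the Mfn2 library, and Prtn3 had 379 against 5 in the Rhot1 library. The osteoclast genes Ctsk and Acp5, highest in the Rhot1 library, had 62 of 66 and 106 of 111 UMIs in a single cell.

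T cell-like cells numbered 299, 97 and 156, and their values are the least precise here. In the Rhot1 library cytotoxic effector genes had a median of 0.45 (0.29 to 0.51), with 12 of 18 higher, including Ifng at a ratio of 2.27 and Fasl at 1.83, and interferon-stimulated genes a median of 0.45 (0.22 to 0.58). With doublets kept these medians fell to 0.0006 and 0.21, so the higher cytotoxic median depends on doublet removal. The Mfn2 library had medians of 0.08 (-0.02 to 0.30) and -0.10 (-0.27 to 0.14) for these lists, from -0.080 to 0.59 and from -0.32 to 0.66 over the alternatives, with Gzma at a ratio of 1.98 and Prf1 at 1.94. Naive and memory genes had a median of -0.74 (-1.12 to -0.23) in the Mfn2 library, with 8 of 11 lower, Tcf7 at 0.332 and S1pr1 at 0.265, and 0.05 (-0.24 to 0.47) in the Rhot1 library. MHC class I presentation genes had medians of -0.37 and 0.24, glycolysis genes 0.39 and -0.21, exhaustion genes -0.09 and 0.19, regulatory T cell genes -0.15 and 0.11, and dissociation stress genes -0.47 and -0.47. The exhaustion and regulatory values had intervals that reached 0 and changed sign under some alternatives. The Rhot1 values for MHC class I and glycolysis turned to -0.06 and 0.06 when doublets were kept, and the Mfn2 value for MHC class I was -0.035 with cells thinned to 1500 UMIs. Genes named by size of ratio mostly rested on single cells. Cma1, a mast cell protease, had 295 of 297 wild-type UMIs in 1 cell, Camp 223 of 227, Ppbp 70 of 72 in the Mfn2 library, and Gzmf 194 of 252 in the Rhot1 library. Ccl1 had 25 UMIs in 2 Rhot1 cells and Serpinb9b 20 UMIs in 8 Mfn2 cells. Thinned to 1500 UMIs, cells with Cd8a or Cd8b1 were 44.5% (37.7 to 51.5), 48.6% (36.7 to 60.7) and 53.3% (44.0 to 62.4) of T cell-like cells. Before thinning, at median depths of 2066, 2458 and 2201 UMIs, they were 38.8%, 47.4% and 53.8%. In thinned tumour-like cells the highest share was 0.0948%.

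**Figure D3:**
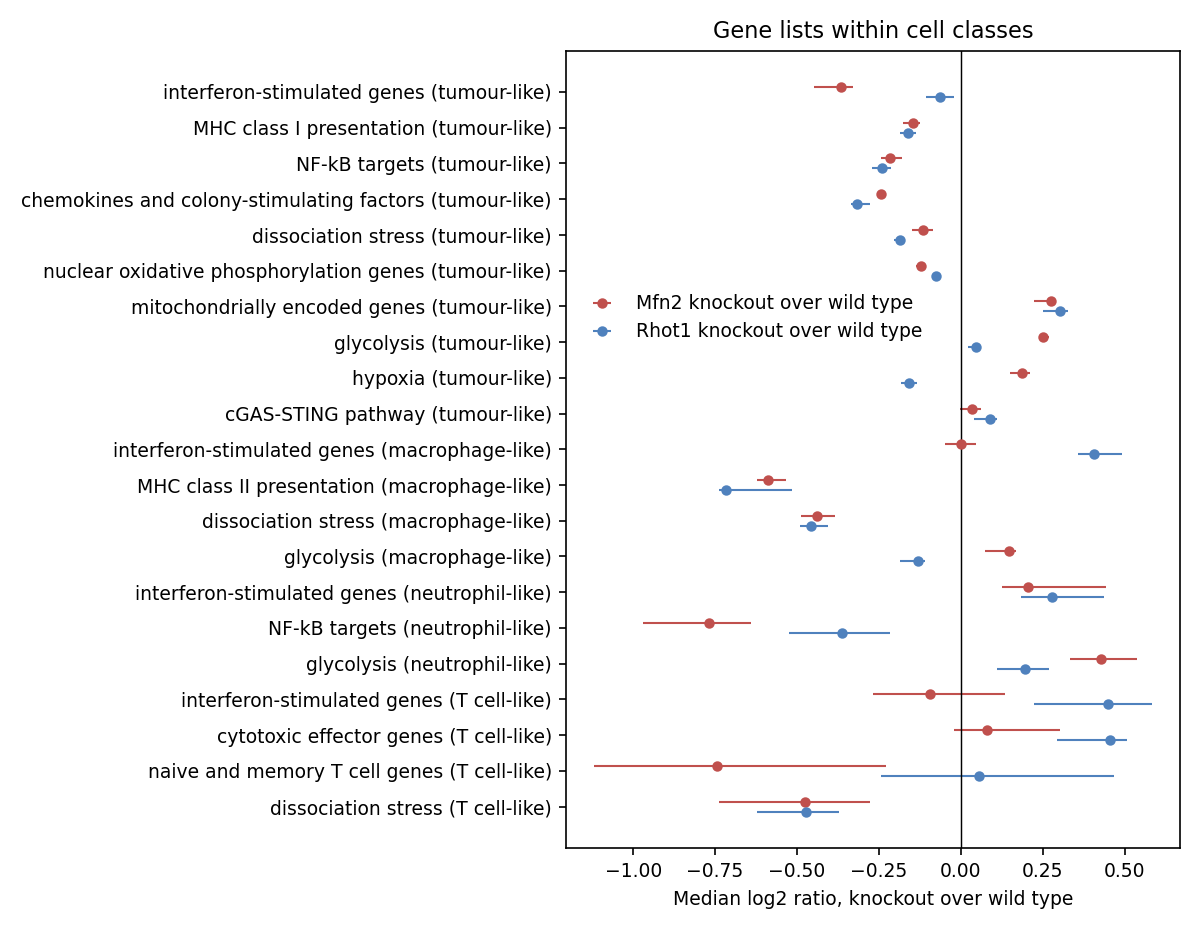
Median log2 ratio of gene lists within cell classes, knockout library over wild-type library, with 1 point per comparison and bars for 95% intervals of counting error. Macrophage-like MHC class II genes lay at -0.59 and -0.72, and macrophage-like interferon-stimulated genes at 0.00 and 0.41, for the Mfn2 and Rhot1 libraries.

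The pools held host cells of both sexes, and the share of cells with Xist differed between the libraries. Among macrophage-like cells with Xist or Y-linked UMIs but not both, those with Xist only were 26.7% (23.7 to 29.9) in the wild-type library, 48.7% (45.3 to 52.2) in the Mfn2 library and 53.8% (50.5 to 57.2) in the Rhot1 library. Y-linked UMIs, which the tumour-like cells also carry, were found in 5.17%, 3.60% and 4.67% of macrophage-like cells with Xist and in 41.4%, 40.3% and 45.3% of those without, so few of them came from RNA of other cells. In T cell-like cells the Xist-only shares were 49.6%, 80.6% and 78.9%, and in tumour-like cells 1.07%, 0.720% and 1.30%. Within the wild-type library the Xist-only share was 2.47% in neutrophil-like cells, so these shares depend on the class and do not give the proportion of each sex among the hosts. An unequal mix of host sexes between the genotypes is possible and was not recorded in the labels used here.

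**Figure D4:**
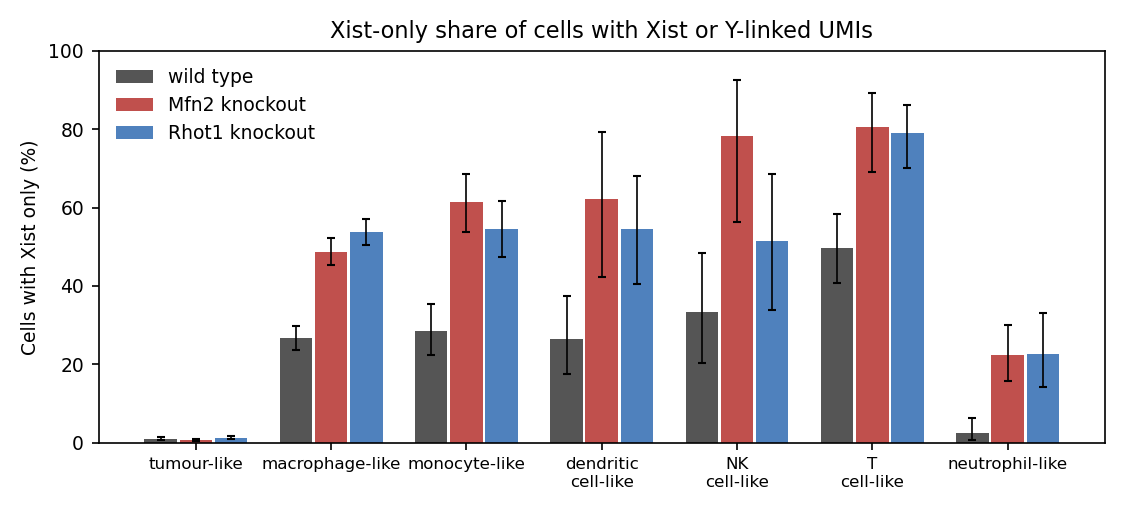
Share of cells with Xist UMIs only, in percent of cells with either Xist or Y-linked UMIs but not both, by class and library. Error bars are exact binomial 95% intervals, and macrophage-like cells lay at 26.7%, 48.7% and 53.8% in the wild-type, Mfn2 and Rhot1 libraries.

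The log2 ratios of the knockouts varied together over genes, as any difference of the shared wild-type pool from both would make them do. In tumour-like cells their covariance over 8317 genes was 0.0251, against 0.000585 in simulations of unchanged groups with counting error alone, a difference of 0.0245, and the correlation across genes was 0.794 against 0.552. In macrophage-like cells the covariance over 8115 genes was 0.0295 against 0.00580, a difference of 0.0237, with correlations of 0.604 and 0.453. Directly compared, the Mfn2 library was lower than the Rhot1 library in interferon-stimulated genes, with medians of -0.23 (-0.28 to -0.20) in tumour-like cells and -0.41 (-0.46 to -0.32) in macrophage-like cells, and higher in glycolysis genes, with medians of 0.22 in both classes. Genes are not independent replicates. With 1 wild-type library the control could not be split, and all of the excess may come from properties of that library, so it does not show a change common to the knockouts.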

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

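Of the tests given here, those of dilution, host sex, handling, cluster mix and nuclear copies were chosen only after their results were seen, and that of damaged cells was written before.

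Gene lists stood out where the Mfn2 and Rhot1 libraries lay on opposite sides of wild type. In the direct comparison, median log2 ratios of Mfn2 over Rhot1 were 0.33 for hypoxia genes, -0.20 for S phase genes and -0.16 for G2/M phase genes in tumour-like cells. They were 0.22 for glycolysis genes and -0.39 for G2/M phase genes in macrophage-like cells, and -0.65 for MHC class I presentation genes and 0.66 for glycolysis genes in T cell-like cells. These differences were not tested, since each genotype has 1 library. Only glycolysis in macrophage-like cells kept both directions under every alternative run. With clusters weighted alike, the Rhot1 values in tumour-like cells turned to 0.099 for hypoxia and -0.023 for G2/M phase, so both depend on cluster mix. Cluster 2, with Adm, Ndrg1 and Egln3 of the hypoxia list among its leading genes, held 14.6%, 17.6% and 7.81% of the wild-type, Mfn2 and Rhot1 class. Cluster 9, led by Cenpf and Cenpe of the G2/M list, held 6.66%, 6.49% and 11.5%. Mfn2 S phase and G2/M phase in tumour-like cells turned to 0.009 and 0.040 at Leiden resolution 0.5. With each library clustered on its own they turned to 0.030 and 0.12. With doublets kept, Mfn2 G2/M phase in macrophage-like cells was 0.0015, and Rhot1 MHC class I and glycolysis in T cell-like cells were -0.062 and 0.061.

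Unnamed clusters, which the main class comparisons leave out, stood out where their share of kept cells was above that of the wild-type library. Cluster 12, with tumour markers and shallow cells, was 1.42 times its wild-type share in the Mfn2 library and 1.48 times in the Rhot1 library. Its median mitochondrial share was 8.56%, against 0.957% to 1.63% in the tumour-like clusters, and mt-Rnr1 and mt-Cytb were among its leading genes. Cluster 14, with tumour markers and shallow cells, was 1.49 times its wild-type share in the Rhot1 library. Cluster 21, with macrophage markers, was 1.85 times its wild-type share in the Mfn2 library and 3.21 times in the Rhot1 library. It held only 21, 41 and 68 cells, with a median of 870 UMIs and the tumour marker Krt8 among its leading genes.

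The lower share of T cell-like cells could arise from more tumour cells in the suspension. Among cells outside tumour-marker clusters the ratio to wild type was 0.385 (0.307 to 0.481) for Mfn2 and 0.692 (0.574 to 0.834) for Rhot1, which argues against dilution by tumour cells as the whole cause. Unequal host sex is another candidate. In the wild-type library, T cell-like cells per 100 macrophage-like cells numbered 29.5 with Xist only and 10.9 with Y-linked UMIs only. The order was the same for Mfn2 (13.4 against 3.07) and Rhot1 (18.3 against 5.72). Xist-only shares were larger in both knockout libraries, which would raise the T cell-like share if these kinds of cells stood for host sex alone. Detection also differed by class. In the wild-type library Y-linked UMIs were found in 28.6% of T cell-like cells without Xist and 41.4% of macrophage-like ones. Over cells of more than 3000 UMIs the order held but was closer for Rhot1 (5.75 against 3.27). The order therefore decides nothing about host sex. Cells of each sex also come from different mice, which limits any reading by host sex. The ratio of T cell-like to macrophage-like cells was compared within cells with Xist only and with Y-linked UMIs only, over all cells and over cells of more than 3000 UMIs. Unequal sex alone would leave a ratio of 1 within each kind of cell. In Mfn2 cells with Xist only the ratio was 0.455 (0.306 to 0.676) over all cells and 0.364 (0.209 to 0.635) over the deeper ones, and with Y-linked UMIs only 0.281 (0.153 to 0.516) and 0.250 (0.0857 to 0.729). In Rhot1 cells with Xist only it was 0.621 (0.433 to 0.889) and 0.322 (0.186 to 0.556). These values argue against host sex as the whole cause in both libraries. Rhot1 cells with Y-linked UMIs only gave 0.524 (0.320 to 0.856) over all cells and 0.719 (0.353 to 1.46) over the deeper ones. The latter rests on 12 and 23 T cell-like cells, so for the deeper cells this ratio alone decides nothing. Differences between single mice or sorts and an effect of the genotype stay open and were not tested.

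Dissociation stress genes were lower in both knockout libraries, as handling of the wild-type suspension could produce. The medians were below 0 in all 5 classes and both comparisons, nearest 0 at -0.12 (-0.15 to -0.08) in tumour-like cells of the Mfn2 library. These are the values that prompted the explanation, so they do not test it, and with 1 suspension per genotype handling cannot be told apart from an effect of the genotype. With cells thinned to 1500 UMIs that median was 0.0050, which weakens the pattern in this class. A different mix of macrophage-like clusters was argued against, because weighting clusters alike left medians of -0.51 for Mfn2 and -0.47 (-0.50 to -0.42) for Rhot1.

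Mitochondrially encoded RNA was higher in tumour-like cells of both knockout libraries, which could arise from reads shared with nuclear copies. Members without a shared stretch had medians of 0.124 (0.101 to 0.146) for Mfn2 and 0.34 for Rhot1, against nuclear copies as the whole cause. These members did not move together in the Mfn2 library, where mt-Cytb was at 0.43 and mt-Nd6 at -0.33. Damaged cells that lost cytoplasmic RNA stay open. Tumour-like cells of 10000 UMIs or more had medians of 0.28 (0.24 to 0.29) and 0.30, but they hold from 94.0% (Mfn2) to 95.7% (Rhot1) of the UMIs of the class, so this cut hardly changes the sums and decides nothing. Other values rose as well: barcodes over the limit on mitochondrial UMIs numbered 85, 124 and 170 in the wild-type, Mfn2 and Rhot1 libraries, and the median mitochondrial share per barcode was 0.987%, 1.18% and 1.38%. In macrophage-like cells that share was 0.843%, 0.967% and 1.11%, so the rise was not particular to tumour-like cells. In neutrophil-like cells it was 0.511%, 0.521% and 0.661%, while the list median there was -0.56 for Mfn2. Cluster 12, outside the class, had a median mitochondrial share of 8.56%. It held 2.59%, 3.68% and 3.83% of kept cells in the wild-type, Mfn2 and Rhot1 libraries. Damage therefore cannot be told apart from an effect of the host genotype, which was not tested.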

How the results depend on the processing

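Alternatives that add the unnamed tumour-marker clusters, leave them out of the denominator, leave out the small deep neutrophil-like cluster or leave out the cell with most UMIs of a gene or list were chosen after the data were seen. Values are log2, Mfn2 before Rhot1 over wild type where a pair is given, and except where stated the cause was not tested. No paired analysis was possible because each genotype has 1 pooled library. Of 1465 list values, 997 stayed within the counting interval, 435 moved beyond it and 33 changed sign from a median whose interval excluded 0. Of those that moved, 21 lay across 0 from a median whose interval reached 0. Of 880 values of named genes, 488 stayed, 385 moved and 7 changed sign, and of 190 share values, 127 stayed, 45 moved and 18 changed sign. The T cell-like share stayed below wild type under every alternative run, from -1.74 to -1.18 for Mfn2 and from -0.99 to -0.50 for Rhot1.

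Tumour-like shares were 0.40 and 0.44 with the stricter filter, 0.18 and 0.19 at resolution 0.5, 0.49 and 0.49 at resolution 2, -0.088 and 0.12 with each library clustered on its own, 0.60 and 0.48 by marker score, 0.53 and 0.48 thinned to 1500 UMIs, and 0.18 and 0.23 with the unnamed tumour-marker clusters. The Rhot1 share was 0.34 without neutrophil-like cells. Marker score named 14.1%, 21.4% and 19.7% of the wild-type, Mfn2 and Rhot1 cells tumour-like.

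Without tumour-like cells in the denominator, shares were 0.15 and 0.14 for macrophage-like cells, 0.042 and 0.032 for monocyte-like cells, 0.13 and 0.12 for both together, and -1.27 and -0.50 for T cell-like cells, by the construction of the denominator. Without all tumour-marker clusters they were 0.041 and 0.11 for macrophage-like cells, 0.0019 for Rhot1 monocyte-like cells, 0.020 and 0.091 for both together, and -0.53 for Rhot1 T cell-like cells.

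With each library clustered on its own, monocyte-like shares were 0.34 and 0.74, the Rhot1 neutrophil-like share -5.29 and the Mfn2 T cell-like share -1.18. In tumour-like cells of Mfn2, S phase was 0.030 and G2/M phase 0.12. Neutrophil-like values for Rhot1 were -1.94 for interferon-stimulated genes, -1.02 for glycolysis and 2.31 for granule genes, and mature neutrophil genes were 0.18 for Mfn2. Rhot1 mature neutrophil genes were -3.52. Monocyte-like MHC class II was 0.51 for Rhot1, interferon-stimulated genes were -1.35 for Mfn2, and T cell-like Cma1 0.13 for Mfn2.

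By marker score, NK cell-like shares were -0.036 and 0.13, dendritic cell-like shares -0.57 and -0.081, and B cell-like shares were 0.25 and 0.70. Tumour-like interferon-stimulated genes were -0.12 and 0.26, and Rhot1 S phase -0.0094. Mfn2 macrophage-like hypoxia was 0.068, Mfn2 neutrophil-like interferon-stimulated genes -0.039 and Rhot1 Acp5 -0.29.

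Thinned to 1500 UMIs, the Mfn2 neutrophil-like share was -0.066, and in Mfn2 tumour-like cells interferon-stimulated genes were -0.22 and dissociation stress 0.0050. In Mfn2 T cell-like cells Ppbp was -0.73 and Camp 0.069. Most neutrophil-like cells hold fewer UMIs than this depth, which limits their values.

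With clusters weighted alike, tumour-like interferon-stimulated genes were -0.13 and 0.023, Rhot1 hypoxia 0.099 and Rhot1 G2/M phase -0.023, and neutrophil-like granule genes 0.069 and 0.012. As the mean over cells, tumour-like interferon-stimulated genes were -0.51 and -0.16 and Rhot1 granule genes 0.18. Mfn2 tumour-like interferon-stimulated genes were -0.48 at a pseudocount of 1 CPM, -0.26 at 20 CPM, -0.29 with no minimum and -0.32 at resolution 2. For Rhot1 they were -0.0017 at resolution 0.5, -0.013 at resolution 2 and -0.0028 with the unnamed tumour-marker clusters.

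Mfn2 S phase and G2/M phase in tumour-like cells were 0.009 and 0.040 at resolution 0.5, and 0.0037 and 0.047 with the unnamed tumour-marker clusters. In Rhot1 tumour-like cells the cGAS-STING pathway was -0.0068 with no minimum, glycolysis -0.0099 with DESeq2 size factors and hypoxia 0.029 with the stricter filter. Rhot1 neutrophil-like interferon-stimulated genes were -0.17 at resolution 2. With doublets kept, Mfn2 macrophage-like tumour-associated genes were -0.022, hypoxia 0.025 and G2/M phase 0.0015, and Rhot1 T cell-like MHC class I was -0.062, glycolysis 0.061 and cytotoxic effector genes 0.0006.

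Without the small deep cluster, neutrophil-like granule genes were 0.92 and 0.61 and Rhot1 Acp5 -0.40, so this cluster carried the lower granule values and the higher Acp5 value. Acp5 was -0.38 with no filter and -0.27 without its top cell. The excess covariance of the knockouts in tumour-like and macrophage-like cells was 0.0128 and 0.0124 at a pseudocount of 20 CPM and 0.0253 and 0.0319 at a minimum of 50 CPM.

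Some alternatives gave no value. With each library clustered on its own no Mfn2 cluster was named NK or B cell-like, and after thinning no cell was named B cell-like. At a minimum of 50 CPM too few members were left for tumour-like interferon-stimulated genes, and there and by marker score for macrophage-like haemoglobin genes.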

Other observations

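No test is reported here, only values of cells outside the comparisons and Xist-only shares of neutrophil- and macrophage-like cells.

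Plasmacytoid dendritic cell-like cells numbered 14 in the wild-type library, 3 in the Mfn2 library and 11 in the Rhot1 library. Cluster 24, with endothelial and stromal genes, held 26, 8 and 37 cells. Among neutrophil-like cells with Xist or Y-linked UMIs but not both, 2.47%, 22.4% and 22.6% had Xist only, against 26.7%, 48.7% and 53.8% of macrophage-like cells in the same libraries.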
